A study of Mus musculus with 9 samples.

How the data were processed

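RNA from marrow endothelial cells of young control, aged control and aged Thbs1-knockout-labelled mice was analysed, with 3 libraries per group. Per the labels' protocols, mice received an antibody to VE-cadherin, an endothelial junction protein, in vivo before the cells were isolated by flow cytometry, and libraries were made from low-input RNA with a full-length cDNA kit. Groups and replicate numbers come from the labels.

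The authors deposited FPKM values, fragments per length of gene and depth of library, rounded to 2 decimals, for 52183 genes. Per the submitters' processing notes, FastQC 0.11.5, STAR and edgeR were used, with the builds GRCm38 and mm10 named and no role given for each. Counting rules, strand setting and treatment of reads that match several places are not given in the sources used here. Values of genes that overlap others or have near-identical copies are therefore uncertain. All 52183 gene identifiers matched the GENCODE M21 annotation on GRCm38, which gave coordinates and exon lengths. No column lacked a sample.

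Depth was recovered from the deposited FPKM. In genes of 60 to 400 bases, low values were whole multiples of what 1 fragment is worth, within a tolerance of 0.1, for 99.5% to 99.8% of 1059 to 1703 values per library. The recovered depth was 22870000, 22860000 and 23890000 fragments in the young controls, 22160000, 22910000 and 24590000 in the aged controls, and 28010000, 30400000 and 27230000 in the libraries labelled knockout. No pair of libraries held identical values.

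Values were tested as log2(FPKM + 1), with a pseudocount of 1, in R 4.3.3 with limma 3.58.1. One fit of all 9 libraries with a mean per group and 6 residual degrees of freedom, followed by eBayes with a trend, gave 3 comparisons. Genes with a mean of at least 1 FPKM over the 9 libraries were kept (11796), and p was adjusted by Benjamini-Hochberg over them with a threshold of 0.05. The count tests made for raw counts were not used because the values are FPKM. The gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists of a comparison. A list needed 5 tested genes. The T and NK cell list had 1 and was not tested. fry called 6, 5 and 2 lists in the comparisons of aged with young, labelled knockout with aged, and labelled knockout with young, and kept 9 of the 31 list calls of camera and lost 22.

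Named genes were fixed by a rule before the data were examined. For each of the first 2 comparisons it took the 6 largest changes in each direction among called genes with at least 5 FPKM in the higher group and no overlap between groups, leaving out predicted, small RNA, pseudogene and antigen receptor names, then up to 3 members of each list with a called gene, up to 2 of other called lists, and Thbs1, Thbs2, Thbs3, Cd36 and Cd47. For labelled knockout against young it took 3 in each direction. By chance 10% of genes show no overlap for 3 against 3, and 35.7%, 23.2% and 22.4% did in the 3 comparisons. Ptprc, and the genes outside this rule in the closing section, were chosen after their values were seen.

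The tests were also run on simulated data for the same 11796 genes, with the residual spread and depths of these libraries and 200 genes changed in the aged controls. Of the genes changed by 1 log2 unit, 80% were called in the simulated comparison of aged with young, and of those changed by 2 units, 99%. The median estimate of genes raised by 1 and 2 units was 0.87 and 1.82. Of 184 calls 5 were genes left unchanged. The error of each gene was drawn independently here, without the correlation of residuals between genes in the real libraries. These shares therefore hold for independent genes and may not hold for the real data. To see how much opposite change the shared aged controls produce, 100 data sets without group effects were drawn that kept the correlation of residuals between genes.

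Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median-ratio and quantile scaling, robust eBayes, array weights, fits of the compared groups alone, the replicate number as a block, each library left out, a threshold of 0.1, and removal of the lists for other cell types. Added after the data were seen were limma voom on fragments recovered from FPKM, length and depth, removal of each library's trend with gene length and GC content, removal of genes within 10 Mb of Thbs1, and division of the aged controls 1 and 2 between the comparisons for the covariance. A count was taken as kept when it stayed within 1.5 times, and a gene or list as reversed when its sign changed while called in either fit. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Reads, exon usage and splicing were not analysed here.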

Results

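Messenger RNA was measured in endothelial cells sorted from the long bones of mice, the cells that line the vessels of the bone marrow. The 9 libraries form 3 groups of 3: young controls aged 3 months, aged controls aged 18 months, and mice aged 18 months that are labelled as knockouts of Thbs1, the gene for the secreted matrix protein thrombospondin-1. The labels name neither the strain nor the part of the gene that was altered. They do not say that each library came from a separate mouse, so p-values measure the spread between these libraries. The recovered depth ran from 22160000 to 30400000 fragments per library, and 11796 genes with a mean of at least 1 FPKM were tested. The young and aged control groups had mean depths of 23210000 and 23220000 fragments, and the group labelled knockout had 28550000. Fold changes are given on the log2(FPKM + 1) scale, which understates changes of genes with low values.

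Thbs1 (ENSMUSG00000040152, GRCm38 chromosome 2, 118111876 to 118127133) was the targeted gene and went against the label. It stood at 4.55, 3.89 and 4.18 FPKM in the young controls, at 0.67, 0.82 and 1.17 FPKM in the aged controls, and at 25.63, 19.45 and 19.84 FPKM in the libraries labelled knockout. The group means were 4.21 ± 0.331, 0.887 ± 0.257 and 21.6 ± 3.46 FPKM (SD, n = 3 each). The level in the libraries labelled knockout was 24.4 times that of the aged controls (log2 fold change 3.58 ± 0.139 SE, limma adjusted p = 2.85e-06), and the aged controls were below the young controls (log2 fold change -1.47 ± 0.139 SE, adjusted p = 0.00385). A two-sided exact permutation test gave p = 0.1 for each pair of groups, the smallest value that 3 against 3 libraries allow. A value per gene does not show which exons were read, so it does not show whether an altered transcript was counted. The related gene Thbs2 and the thrombospondin-1 receptor Cd47 passed the test in no comparison (adjusted p = 0.494 to 1), and Thbs3 was at 0.02 to 0.13 FPKM, below the filter. Cd36, a scavenger receptor that binds thrombospondin-1, fell with age from 500.1 ± 44.2 to 222.5 ± 73.1 FPKM (SD, n = 3, adjusted p = 0.0371). That call was lost in 6 of the 9 fits that left out 1 library. Cd36 stood at 316.2 ± 87.1 FPKM in the libraries labelled knockout, which overlapped the aged controls (adjusted p = 0.228).

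**Figure D1:**
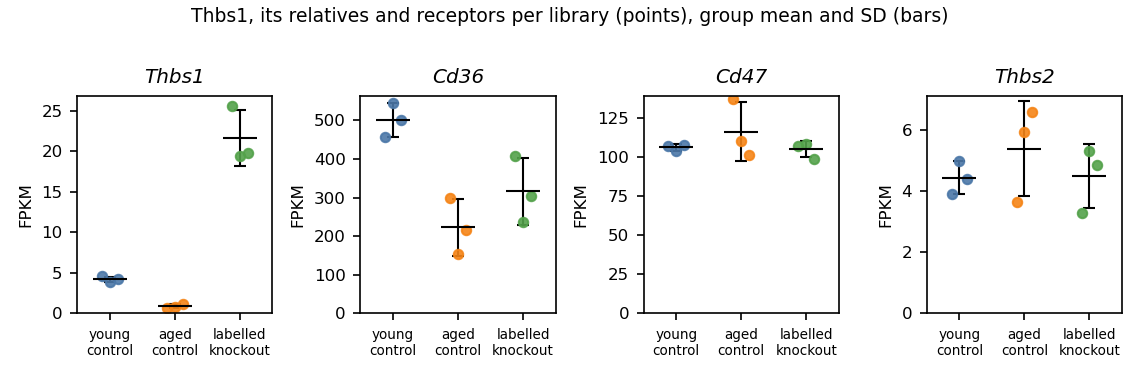
FPKM of Thbs1, Cd36, Cd47 and Thbs2 in each library, by group; points are libraries, the horizontal bar is the mean and the whiskers 1 SD (n = 3). Thbs1 lies at 19.45 FPKM or above in the libraries labelled knockout and at 1.17 FPKM or below in the aged controls.

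The comparison of aged with young controls asks how the marrow endothelium differs with age. Cxcl10, an interferon-induced chemokine, fell from 80.2 ± 32.8 to 16.7 ± 6.44 FPKM (SD, n = 3, log2 fold change -2.20, adjusted p = 0.0168), and the chemokine Ccl12 fell from 33.5 ± 6.34 to 7.67 ± 1.15 FPKM (adjusted p = 0.0166). Sparcl1, a matrix-associated glycoprotein, fell from 22.9 ± 2.47 to 3.49 ± 0.910 FPKM (log2 fold change -2.43, adjusted p = 0.00684). Ibsp, a bone matrix protein, fell from 25.5 ± 11.6 to 4.19 ± 0.473 FPKM. The fall was from 9.76 ± 1.01 to 1.96 ± 0.937 FPKM for BC023105, and from 12.5 ± 1.28 to 2.99 ± 1.76 FPKM for Ednrb, an endothelin receptor. Cygb, a globin, rose from 2.73 ± 0.313 to 14.3 ± 0.183 FPKM (log2 fold change 2.04, adjusted p = 0.0165). The complement receptor C5ar1 rose from 48.9 ± 4.08 to 156.1 ± 34.2 FPKM, and Bin2, Plbd1, Fam174b and the gap junction gene Gjb1 rose to 3.76, 5.65, 3.40 and 4.45 times their young level. Of the 11796 genes, 141 were higher and 330 lower in the aged controls at an adjusted p under 0.05. After median-ratio scaling the split was 238 higher and 196 lower, and after quantile normalization 160 and 199. The count also depended on single libraries: without young control replicate 1, 2 or 3 the calls were 5, 31 and 12, and without the labelled knockout replicate 2 they were 1039. Of the named genes, only BC023105, Egr2 and Thbs1 were called in each of the 9 fits that left out 1 library. The call of C5ar1 was lost in 6 of them and that of Ednrb in 5.

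Of the 27 gene lists fixed before the data were examined and large enough to test, 9 were called with age by camera at a preset correlation of 0.01. None of the 9 was called with an estimated correlation (adjusted p = 0.559 to 0.576), and fry called 3 of them, the NF-kB, stem cell factor and stromal lists. It also called the senescence, thrombospondin receptor and coagulation lists, which camera did not. The thrombospondin receptor list includes Thbs1 itself, and its only called members were Thbs1 and Cd36. The senescence list shares Cxcl1 and Ccl2 with the NF-kB list. In the list of NF-kB targets and inflammatory genes, 5 of 27 measured members fell and none rose (camera adjusted p = 0.00925), and 10 fell when adjusted over the list alone. They included the transcription factor Irf1, from 198.3 ± 27.4 to 93.8 ± 6.94 FPKM, the endothelial adhesion molecule Sele (E-selectin), from 519.7 ± 25.7 to 306.1 ± 52.9 FPKM, and the neutrophil chemoattractants Cxcl1 and Cxcl2. In the interferon list, 3 of 31 members fell and 1, the antiviral tether Bst2, rose from 123.2 ± 12.6 to 190.3 ± 22.9 FPKM (adjusted p = 0.00702). Adjusted over the list alone, 13 fell and 1 rose. Of the 22 measured endothelial factors that act on haematopoietic stem cells, 4 fell, among them the chemokine Cxcl12, from 46.1 ± 3.72 to 28.1 ± 4.97 FPKM, and Esm1, from 10.2 ± 1.40 to 3.54 ± 0.882 FPKM (adjusted p = 0.00588). Adjusted over the list alone, 6 fell. The lists share members, so their calls are not independent. Of the called stem cell factors, Sele is also in the NF-kB list, Esm1 in the angiogenesis list and Cxcl12 in the stromal list. Of 22 basement membrane and matrix genes, 4 fell, including the laminin chain Lama4, from 5.70 ± 0.604 to 1.69 ± 0.673 FPKM, and Mmrn1 (adjusted p = 0.0167), and 11 fell and 1 rose when adjusted over the list alone. The marrow stromal, osteoblast and fat cell list was also lower (median log2 fold change -0.59, adjusted p = 0.0167), with Adipoq, the adipocyte hormone adiponectin, at 13.1 ± 1.18 and 5.97 ± 0.655 FPKM. The estimated correlation of this list was 0.001, below the preset 0.01, yet camera then gave an adjusted p of 0.559. A call lost with an estimated correlation therefore does not by itself show that the genes of a list are correlated.

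Lists that were higher in the aged controls held few single genes that passed. The antigen presentation list was called (median log2 fold change 0.50, adjusted p = 3.87e-06) with no called member among 19, also when adjusted over the list alone. The class II gene H2-Ab1 stood at 15.2 ± 3.51 and 46.9 ± 19.7 FPKM (adjusted p = 0.0813). Nuclear-encoded respiratory chain genes had a median of 0.23 with 0 of 31 members called, none also when adjusted over the list alone (list adjusted p = 3.87e-06). Of the 24 genes of the unfolded protein response, 3 rose: Creld2, Sdf2l1 and Edem1, with log2 fold changes of 0.94, 1.01 and 0.37 (list adjusted p = 0.00171). Adjusted over the list alone, 8 rose and 1 fell. The glycolysis list was called as higher (median 0.22, adjusted p = 0.0217), while its single called member, Pfkfb3, which activates glycolysis, fell from 8.88 ± 0.450 to 5.96 ± 0.597 FPKM. The remaining lists were not called. Their medians were -0.18 for pan-endothelial genes, in which the tight junction gene Cldn5 rose from 483.6 ± 20.02 to 810.3 ± 49.6 FPKM and the transcription factor Erg fell, 0.05 for sinusoidal and 0.07 for arterial markers, -0.15 for senescence and -0.12 for thrombospondin receptor genes. The medians were -0.16 for transforming growth factor beta genes, -0.03 for nitric oxide, -0.23 for angiogenesis, 0.17 for mitochondrially encoded transcripts, -0.12 for the cell cycle and -0.16 for haemostasis genes. The immediate early list had a median of -0.01, with the transcription factors Egr2, Nr4a2 and Atf3 lower and Jund higher. Among lists for other cell types, the median was 2.43 for B-lineage and plasma cell genes (adjusted p = 0.133), 0.53 for monocytes and macrophages, 0.41 for neutrophils, -0.01 for megakaryocytes, -0.46 for smooth muscle and 0.00 for erythroid genes, whose median of -0.001 and test differ in sign. Ptprc, the pan-leukocyte gene, was at 0.03 to 0.13 FPKM in the 9 libraries. This 1 gene does not show how much RNA came from other cells. The immunoglobulin gene Igkc, given in the closing section, had a higher mean in the aged than in the young controls, with a wide spread.

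**Figure D2:**
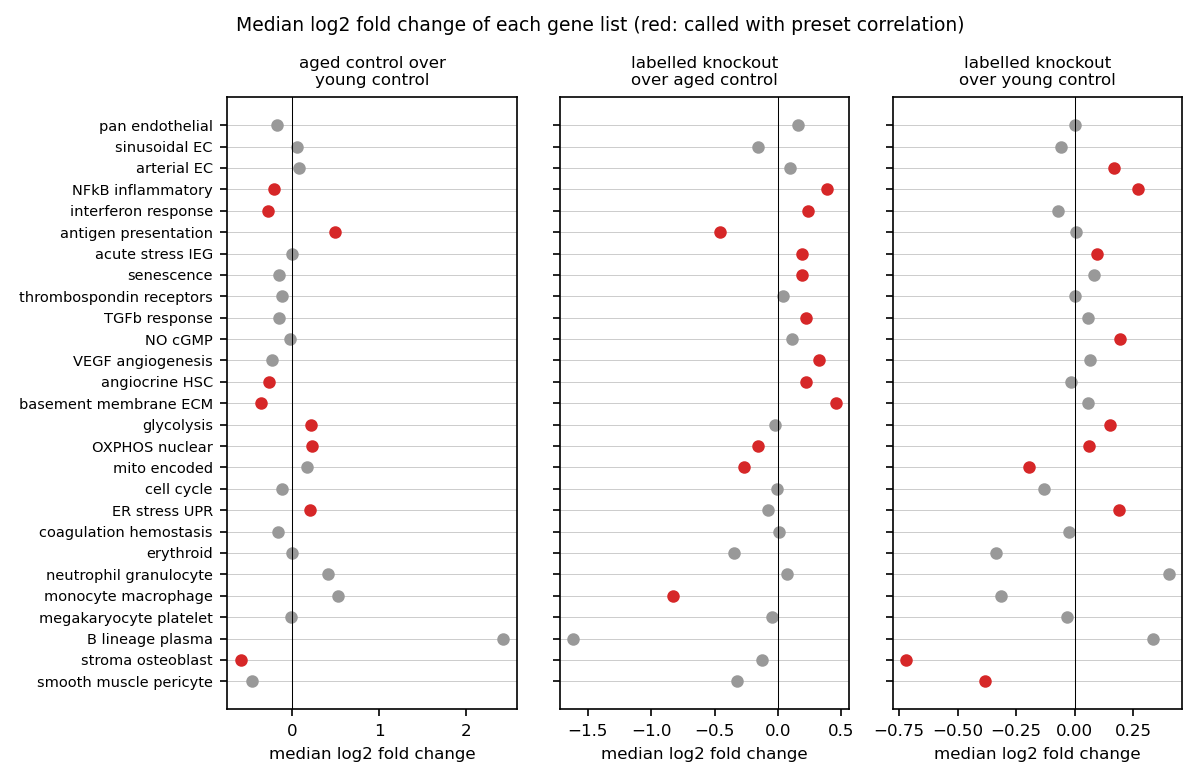
Median log2 fold change of the tested members of each of the 27 gene lists (x axis, which differs between panels) in the 3 comparisons; red points were called by camera at a preset correlation of 0.01, grey points were not. None of the red points was called when the correlation was estimated.

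The comparison of the libraries labelled knockout with the aged controls asks what the labelled genotype changes at 18 months, with the reservation that Thbs1 itself was higher in them. Many of the genes that were lower in the aged controls were higher here. Cxcl10 rose from 16.7 ± 6.44 to 166.2 ± 39.1 FPKM (SD, n = 3, 9.97 times, adjusted p = 0.00123), Ccl12 to 56.6 ± 24.6 FPKM (adjusted p = 0.00224), Sparcl1 to 25.7 ± 11.5 FPKM (adjusted p = 0.00224) and Cxcl1 from 18.9 ± 9.20 to 76.9 ± 15.4 FPKM (adjusted p = 0.00885). Tmem87a, a membrane protein gene on chromosome 2 and 2.24 Mb from Thbs1, rose from 0.993 ± 0.308 to 15.2 ± 2.09 FPKM (adjusted p = 7.95e-06). Bin2 fell from 19.8 ± 3.06 to 3.90 ± 3.03 FPKM (adjusted p = 0.00691) and Cygb from 14.3 ± 0.183 to 2.86 ± 2.25 FPKM (adjusted p = 0.00643). The inhibitory immunoglobulin receptor Fcgr2b, a sinusoidal marker, fell from 304.0 ± 65.2 to 90.2 ± 78.6 FPKM (adjusted p = 0.0352), and the lectin Lgals1 from 140.6 ± 45.5 to 37.3 ± 25.01 FPKM. The homeobox gene Meis2, on chromosome 2 and 2.25 Mb from Thbs1, stood at 6.33 ± 0.919 and 0.0567 ± 0.0462 FPKM, and the mitochondrially encoded mt-Nd3 at 5.13 ± 1.51 and 0.230 ± 0.141 FPKM. The value of mt-Nd3 is uncertain because nuclear copies of mitochondrial genes can share its reads. One library stood apart: Fcgr2b was at 180.85 FPKM in replicate 2 labelled knockout and at 41.97 and 47.76 FPKM in the other two, Bin2 at 7.37 against 1.79 and 2.54, and Cygb at 5.45 against 1.38 and 1.75. In all, 328 genes were higher and 237 lower. Without replicate 2 labelled knockout there were 596 and 563, but without replicate 1 there were 134 and 63, and without replicate 3 146 and 78. The Fcgr2b call was lost in 8 of the 9 fits that left out 1 library. The fit of these 6 libraries alone called 112 higher and 37 lower.

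**Figure D3:**
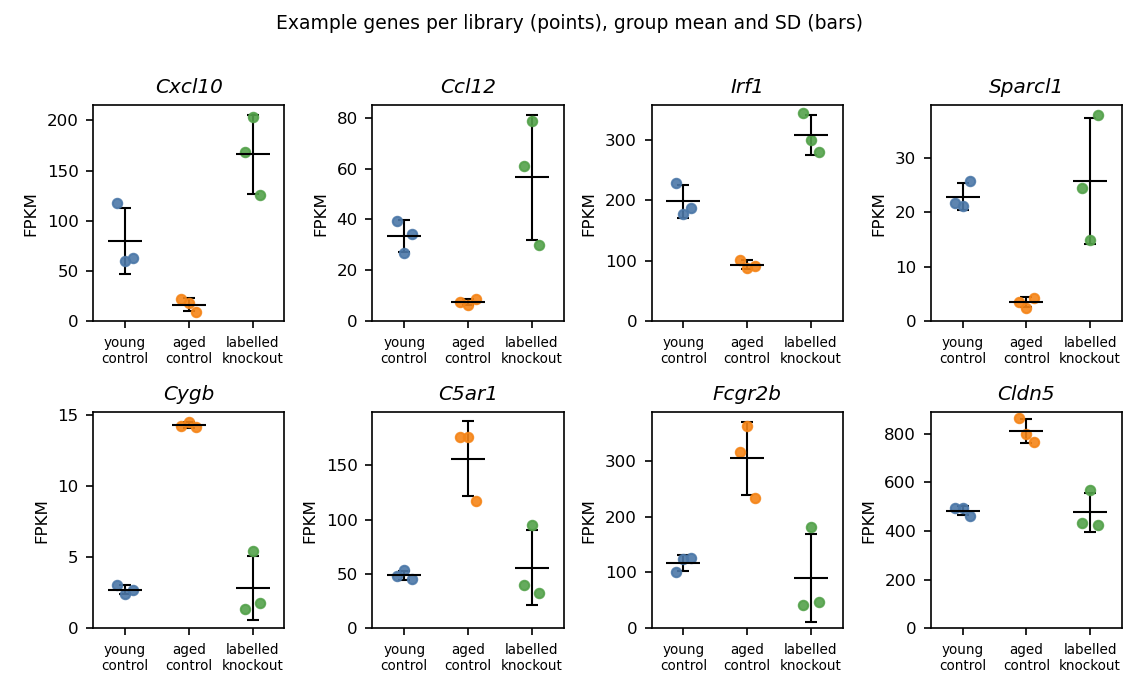
FPKM of 8 genes in each library, by group; points are libraries, the horizontal bar is the mean and the whiskers 1 SD (n = 3). Cxcl10 is below 22 FPKM in the aged controls and at 125.77 FPKM or above in the libraries labelled knockout, and Fcgr2b is spread from 41.97 to 180.85 FPKM among the latter.

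In this comparison 12 lists were called by camera, and none with an estimated correlation (adjusted p = 0.452 to 0.474). Of 27 NF-kB and inflammatory genes, 8 rose and none fell (camera adjusted p = 1.19e-06), and 11 rose when adjusted over the list alone. Irf1 went from 93.8 ± 6.94 to 307.8 ± 33.1 FPKM, and Nfkbiz, an inducible nuclear regulator of NF-kB, rose 1.99 times. Of 31 interferon genes, 5 rose and none fell (adjusted p = 0.00196), with Mx2 at 0.427 ± 0.0404 and 2.48 ± 0.362 FPKM, and 7 rose when adjusted over the list alone. Of 25 immediate early and heat shock genes, which cell isolation can also induce, 7 rose and 1 fell (adjusted p = 0.0028). Egr2 rose from 19.1 ± 0.875 to 58.2 ± 2.29 FPKM, Atf3 2.04 times and Egr1 1.62 times, and 12 rose and 4 fell when adjusted over the list alone. Of 22 senescence-associated genes, 5 rose, among them the cell cycle inhibitor Cdkn1a, from 176.9 ± 22.7 to 332.9 ± 27.2 FPKM, and the chemokine Ccl2 (list adjusted p = 0.0309, 5 adjusted over the list alone). Of 23 angiogenesis genes, 4 rose, including Vegfa, from 22.4 ± 0.218 to 34.1 ± 2.59 FPKM, Adm and the Notch ligand Jag1 (adjusted p = 0.00206), and 6 rose and 1 fell when adjusted over the list alone. Of 22 stem cell factors, 4 rose, with Dll1 and Igfbp3 among them (adjusted p = 0.00649, 7 adjusted over the list alone). The others were Sele, also in the NF-kB list, and Jag1, also in the angiogenesis list, and Igfbp3 is also in the senescence list. Of 22 basement membrane genes, 5 rose, with the collagen chain Col4a2 at 38.0 ± 16.7 and 93.8 ± 23.96 FPKM (adjusted p = 0.00131, 10 higher and 3 lower adjusted over the list alone). The transforming growth factor beta list was higher with none of 25 members called, also adjusted over the list alone (median 0.22, adjusted p = 0.00501).

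The lists called as lower in the libraries labelled knockout were antigen presentation, nuclear-encoded respiratory chain, mitochondrially encoded transcripts and monocyte or macrophage markers. Of the 12 called lists fry kept 4, NF-kB, immediate early, senescence and mitochondrially encoded, and lost antigen presentation (adjusted p = 0.165) and respiratory chain (adjusted p = 0.166) among others. It also called the thrombospondin receptor list (fry adjusted p = 0.00477), which camera did not and whose only called member was Thbs1 itself. Of 19 antigen presentation genes, 1 fell, H2-Eb1, from 19.3 ± 4.46 to 6.31 ± 4.95 FPKM (list adjusted p = 0.000122, 6 adjusted over the list alone). Replicate 2 labelled knockout stood apart here too, with H2-Eb1 at 12 FPKM against 3.95 and 2.98 in the other two, H2-Ab1 at 33.63 against 8.96 and 8.72, and H2-Aa at 16.27 against 4.11 and 5.09. Of the 9 fits that left out 1 library, the calls of H2-Eb1, Dnase1l3 and Adipoq were lost in 8 and that of Sdhc in 7. Of 31 respiratory chain genes, 1 fell, Sdhc, from 72.5 ± 3.93 to 54.8 ± 4.35 FPKM (list adjusted p = 0.00178, 1 adjusted over the list alone). Of 9 mitochondrially encoded transcripts, 3 fell, mt-Nd3, mt-Co3 and mt-Co1 (list adjusted p = 0.000729, 4 adjusted over the list alone). The value of mt-Nd3 is uncertain because nuclear copies can share its reads. mt-Co3 stood at only 3.22 and 1.54 FPKM, and mt-Co1 at 1241 and 908.9 FPKM. The call of mt-Co1 was lost in 7 of the 9 fits that left out 1 library. Whether this list reflects a change of mitochondrial transcripts or the placing of reads was not tested. The monocyte list had a median of -0.83 with none of 6 members called and 1 lower adjusted over the list alone (adjusted p = 0.036). Its call was lost in 4 of the 9 fits that left out 1 library. Among the lists not called, the B-lineage median was -1.61, sinusoidal markers -0.16 with Fcgr2b and Dnase1l3 lower, pan-endothelial genes 0.16 with Sox7 higher and Cldn5 lower, and stromal genes -0.13 with Adipoq lower. Without aged control replicate 1, 4 lists were called in place of 12.

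The comparison of the libraries labelled knockout with the young controls differs in age and labelled genotype together. It gave 10 genes higher and 15 lower, and several of them lie on chromosome 2 beside Thbs1. Tmem87a (120355312 to 120404113) rose from 1.52 ± 0.258 to 15.2 ± 2.09 FPKM (SD, n = 3, adjusted p = 5.09e-05). Gchfr (119167773 to 119172390), a regulator of tetrahydrobiopterin synthesis, rose from 30.5 ± 2.91 to 89.6 ± 10.8 FPKM, against 42.2 ± 4.91 FPKM in the aged controls (adjusted p = 0.00044). Thbs1 was 5.14 times its young level (adjusted p = 0.000145). Adipoq fell from 13.1 ± 1.18 to 3.76 ± 0.682 FPKM (adjusted p = 0.00044), and the secreted glutathione peroxidase Gpx3 from 34.4 ± 7.63 to 11.8 ± 1.18 FPKM (adjusted p = 0.0214). The endosomal sorting gene Snx5, also on chromosome 2 (144250123 to 144270906), fell from 67.0 ± 1.82 to 27.5 ± 1.63 FPKM (adjusted p = 0.0115). Within 10 Mb of Thbs1, 6 of 118 tested genes other than Thbs1 were called, against 18 of 11677 elsewhere (Fisher's exact test, two-sided, odds ratio 34.6, 95% confidence interval 11 to 93.3, p = 1.03e-07). In aged against young controls the same window held 6 called genes of 118, against 464 of 11677 elsewhere (Fisher's exact test, odds ratio 1.29, p = 0.476). Without the genes of this window, 5 genes were higher and 12 lower. The calls for Gpx3 and Snx5 were lost without young control replicate 1 or 2, among others.

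**Figure D4:**
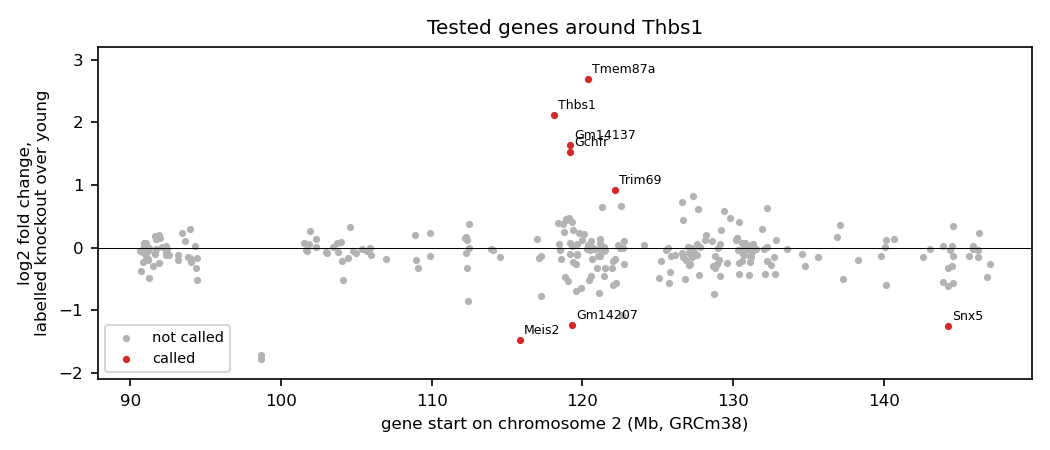
Log2 fold change of the libraries labelled knockout over the young controls (y axis) for tested genes within 30 Mb of Thbs1, by the start of the gene on chromosome 2 (x axis, Mb, GRCm38); red points passed an adjusted p of 0.05. The called genes cluster around Thbs1, with Snx5 26.14 Mb away.

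Of the 27 lists, 10 were called in this comparison by camera, none with an estimated correlation (adjusted p = 0.0645 to 0.694), and 2, the stromal and the smooth muscle and pericyte lists, with fry. The marrow stromal list was lower, with a median of -0.72 and 2 of 9 members called, Adipoq and Cxcl12 (adjusted p = 1.69e-05 at the preset correlation and 0.0645 with an estimated one), and smooth muscle and pericyte genes had a median of -0.38 with none of 6 called (0.000209 and 0.0927). Adjusted over the list alone, 5 and 3 members were lower. The unfolded protein response list was higher, with 0 of 24 members called and 4 adjusted over the list alone (median 0.19, adjusted p = 2.32e-06). The immediate early (0.09), NF-kB (0.27), glycolysis (0.15), arterial (0.17), nitric oxide (0.19) and respiratory chain (0.06) lists were called as higher by their medians given here, with no called member over all genes, and mitochondrially encoded transcripts as lower (-0.20, with mt-Nd3 called). The value of mt-Nd3 is uncertain because nuclear copies can share its reads. Adjusted over the list alone, 6 immediate early, 4 NF-kB and 1 nitric oxide genes were higher. The interferon list was not called, and its median of -0.07 and its test differed in sign.

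Changes with age and changes in the libraries labelled knockout went in opposite directions for many genes. Of the 330 genes lower in the aged controls, 145 (43.9%) were higher in the libraries labelled knockout than in the aged controls, and of the 141 higher genes, 70 (49.6%) were lower. Independent lists of these sizes share 9.18 and 2.83 genes, and 1 gene, Adipoq, changed in the same direction in both, with its call in labelled knockout against aged lost in 8 of the 9 fits that left out 1 library. Both comparisons use the same 3 aged control libraries, which produces opposite fold changes by chance. In 100 simulated data sets without group effects no gene was called in opposite directions. But 98 of them had no call at all in aged against young and 99 none in labelled knockout against aged. The highest numbers of calls in a set were 1285 and 2034, more than the 471 and 565 observed. A set without group effects can thus, rarely, give a longer list of calls than the real one. So the simulated sets do not show how many of the 215 the shared controls produce. The covariance of the fold changes across genes was -0.109, against a simulated mean of -0.0298, with a difference of -0.0797. The lowest simulated covariance was -0.105, so the observed value lay just beyond the simulated range. The correlation across genes, which are not independent replicates, was -0.77, inside the simulated range of -0.96 to 0.37. With the 3 aged controls divided 1 and 2 between the comparisons, the covariance averaged -0.071 over the 6 divisions (-0.075 to -0.0632), against a simulated mean of -0.00433 and a lowest simulated value of -0.0659. The calls were not repeated with divided controls, so part of the excess of shared genes may come from the shared libraries. The total of 215 shared genes changed to between 5 and 600 when 1 library was left out, with 5, 27 and 12 without young control replicates 1, 2 and 3.

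**Figure D5:**
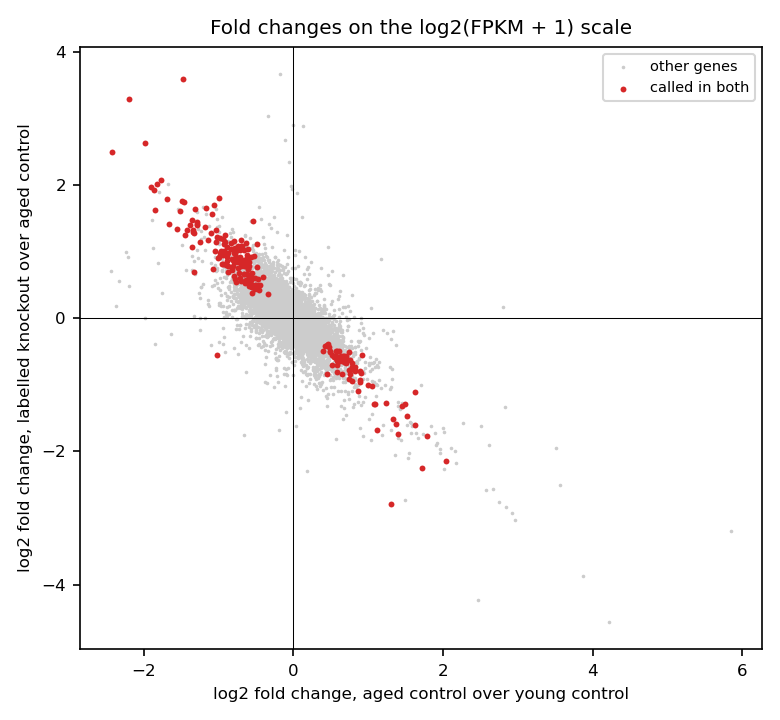
Log2 fold change of each tested gene in aged over young controls (x axis) and in the libraries labelled knockout over aged controls (y axis); red points were called in both. Of the red points, 145 lie upper left, 70 lower right, and 1, Adipoq, lower left.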

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

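Fits with voom, with the length and GC trend removed and without the window around Thbs1, and the division of the aged controls, were chosen after seeing the data. Thbs1 stayed higher in the libraries labelled knockout than in the aged controls in every fit that kept it, from 2.17 with a pseudocount of 5 to 4.62 with voom, and from 3.46 to 3.69 when 1 library was left out. Of the 92 called values of named genes, 33 kept their call in all 9 fits that left out 1 library and none changed sign, and 15 of 31 list calls did so. In aged against young only BC023105, Egr2 and Thbs1 of the named genes kept their call in all 9. There the calls of Gjb1 and Edem1 were lost in 8 of these fits and those of Bin2, Plbd1, Pfkfb3 and Creld2 in 7. Those of C5ar1, Lama4, Mmrn1, Erg and Bst2, among others, were lost in 6, and those of Cxcl12 and Ednrb in 5. In labelled knockout against aged that of Col4a2 was lost in 7. Causes were not tested.

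Counts are given as higher and lower. Aged against young gave 141 and 330, with 6 and 33 without a filter, 238 and 196 with median-ratio scaling, 199 lower with quantile normalization, 846 and 1474 with array weights, 258 higher with 2 groups, and 585 and 1088 at a threshold of 0.1. With 1 library left out it ranged from 0 to 366 and from 5 to 673. Labelled knockout against aged gave 328 and 237, with 108 and 38 without a filter, 1013 and 841 with array weights, 112 and 37 with 2 groups, and 698 and 599 at 0.1, and ranged from 134 to 596 and from 63 to 563. Labelled knockout against young gave 10 and 15, with 7 lower without a filter, 5 and 7 at a mean of 5 FPKM, 227 and 394 with array weights, 16 and 24 at 0.1, 16 higher with the length and GC trend removed and 5 higher without the window around Thbs1, and ranged from 7 to 13 and from 4 to 18. The 215 genes changed in opposite directions became 27 without a filter, 1075 with array weights, 85 with 2 groups and 714 at 0.1, and ranged from 5 to 600. The covariance across all tested genes, -0.109, became -0.206 and -0.0488 with pseudocounts of 0.1 and 5, -0.0451 without a filter, -0.216 with voom and -0.071 with the aged controls divided 1 and 2 between the comparisons, and ranged from -0.133 to -0.091.

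The 9, 12 and 10 called lists became 0, 0 and 0 with an estimated correlation. fry called 5 and 2 in the comparisons with the libraries labelled knockout. Aged against young gave 15 lists without a filter, 14 with quantile normalization and 14 with the length and GC trend removed. Labelled knockout against aged ranged from 4, without aged control replicate 1, to 13. Antigen presentation in labelled knockout against young had a median of 0.005 and was not called, and ranged from -0.186, called as lower without labelled knockout replicate 2 (adjusted p = 0.00223), to 0.193, called as higher without labelled knockout replicate 1 (adjusted p = 0.0182).

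The residual correlations did not show that the replicate numbers pair the libraries. Those of same-numbered libraries of different groups ran from -0.129 to 0.124, and 1 of 9 was over 0.1. Those of differently numbered libraries ran from -0.213 to 0.173, with 3 of 18 over 0.1. With so few libraries per group a pairing is not excluded. With the number as a block, aged against young gave 52 and 131, labelled knockout against aged 156 lower, and 123 genes changed in opposite directions. Depth limits low genes, and values under the filter were not tested.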

Other observations

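The tests of sequencing depth, of DNA around the knockout allele, of the fold change kept after removal of a trend and of divided aged controls, and the margin for the covariance below, were chosen after the results were seen. Ifi208, on chromosome 1 at 173673675 to 173698395, stood at 4.65 FPKM in the young controls, 2.53 in the aged controls and 0.05 in the libraries labelled knockout (adjusted p = 0.000173 against young). Trim69, on chromosome 2 4.05 Mb from Thbs1, stood at 3.01, 1.74 and 6.497 FPKM. The immunoglobulin light chain gene Igkc was at 120.5 ± 202.3, 1328 ± 965.6 and 706.5 ± 828.3 FPKM (SD, n = 3). Ddx3y was at 0 in the 9 libraries. Xist was at 10.49, 9.88 and 11.11 FPKM in the libraries labelled knockout and at 15.15 to 18.96 FPKM in the others.

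Several genes with near-identical copies moved apart from their copy. Pcna-ps2, a processed copy of Pcna on chromosome 19, was at 1.01 ± 0.372, 0.777 ± 0.313 and 21.3 ± 1.18 FPKM in young controls, aged controls and libraries labelled knockout, while Pcna, on chromosome 2, was at 54.5 ± 2.97, 40.2 ± 10.1 and 46.8 ± 0.780 FPKM. Eif3j2, on chromosome 18, was at 0.173, 0.153 and 3.54 FPKM, and Eif3j1, on chromosome 2 at 122028546 to 122056598, at 4.81, 3.29 and 2.86 FPKM. Gm28438, a pseudogene on chromosome 1, was at 0.337, 0.457 and 10.1 FPKM, and mt-Nd3 at 4.42, 5.13 and 0.230 FPKM. No explanation of these values was tested.

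Thbs1 was highest in the libraries labelled knockout and lowest in the aged controls. If DNA around the altered allele differs, a swap of these labels predicts an excess of called genes beside Thbs1 in aged against young controls. The odds ratio there was 1.29 (confidence interval 0.463 to 2.93, Fisher's exact test, p = 0.476). Within 10 Mb of Thbs1, 6 of 118 other genes were called, as many as in labelled knockout against young. With 464 calls elsewhere a small excess could be hidden here. Labelled knockout against aged had 548 calls elsewhere, and 16 of 118 genes in the window were called (Fisher's exact test, odds ratio 3.19, p = 0.000151). An excess of that size could thus be seen beside as many calls. In the libraries labelled knockout against young controls the odds ratio was 34.6 (Fisher's exact test, p = 1.03e-07), with 18 calls elsewhere. DNA around an altered allele that differs from the controls would give this excess in libraries that carry the allele. That is a candidate explanation for the neighbouring genes and perhaps for Thbs1, but the neighbours were seen before this test was written and neighbouring genes are not independent. With such DNA, a swap predicts no excess in labelled knockout against young, where the odds ratio was 34.6. For these neighbouring genes the values therefore argue against a swap of the labels, without excluding it. Whether the altered allele still makes a transcript, and regulation of Thbs1 by age or genotype, stay open.

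More genes were above 0 FPKM in the young controls (25893 ± 654, SD, n = 3) than in the aged controls (21334 ± 712). The group means of depth had a ratio of 0.999, which argues against depth as the cause. Genes with a mean under 0.5 FPKM held 0.473 ± 0.0243% of reads in young and 0.372 ± 0.0247% in aged controls, a ratio of 1.27 with no overlap, as a broad low background in the young libraries, for example from genomic DNA or unspliced RNA, would give. That may account for the difference. Wider transcription in young cells would give the same values and stays open. The libraries labelled knockout, also aged 18 months, had 22834 ± 1504 genes above 0 FPKM at a mean depth of 28550000 fragments. Genes with a mean under 0.5 FPKM held 0.371 ± 0.0151% of their reads. These values set the young group apart from both groups aged 18 months, and do not separate a background from an effect of age.

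The opposite direction of the 2 sets of fold changes was set against the shared aged controls and against a trend with gene length and GC content. The covariance of -0.109 lay below the lowest of 100 simulated values, -0.105, by less than their SD of 0.0238. With the length and GC trend removed it was -0.0961, level with the lowest simulated value of -0.0961 to the digits given and not below it, where the SD was 0.0227. The predictions written beforehand named only the lowest simulated value as the limit. Read that way, the first value counts against the shared controls and the second goes with the trend. A margin of 1 SD was added after both values were seen, because neither is clear of its limit, and with it the covariance excludes neither explanation. The 215 genes called in opposite directions kept a median of 91.7% of their log2 fold change in aged against young after removal of the trend (quartiles 77.3 and 104%) and 94.6% in labelled knockout against aged (86.3 and 103%), all with the same sign, and 157 were still called in opposite directions. This argues against the trend as the whole cause of the changes in these genes, and leaves the shared controls open. With the aged controls divided between the comparisons the mean covariance of -0.071 lay below the lowest simulated value, -0.0659, by less than the SD of 0.0235, so this does not exclude chance or decide on the shared controls. An effect of the labelled genotype on age-related genes stays open.

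The number of called genes was compared with that of the other ways to divide the 6 libraries of a comparison into 3 and 3. For aged against young controls the real division gave 471 genes and the highest other 1, for labelled knockout against aged 565 and 2, and for labelled knockout against young 25 and 3. In each comparison 1 of the 10 divisions, the real one, gave as many genes. With 10 divisions the share cannot fall under 0.05. Each other division also mixes the 2 real groups, so a real difference between them goes into the residual spread. The low counts of the other divisions therefore do not show how many calls arise without a difference, and no conclusion is drawn from them.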
